A study of Mus musculus with 12 samples.

How the data were processed

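RNA from mouse kidney cortex was measured on 12 arrays with 2 colours. Per the labels, the RNA came from 6 numbered cortex samples, 3 called control and 3 called menopausal, and the menopausal samples carry the treatment VCD. In mouse work on menopause these letters commonly stand for vinylcyclohexene diepoxide, a chemical that depletes the follicles of the ovary. Per the labels' protocols, total RNA was extracted on columns, amplified as antisense RNA, copied into cDNA with amino allyl dUTP and coupled to an Alexa Fluor dye. On each array 1 sample carried Alexa Fluor 546 and another carried Alexa Fluor 647. Each cortex sample was hybridised on 4 arrays, 2 with each dye, and 12 of the 15 possible pairs of samples met on an array, 6 of them across groups. The pairs of the same number in both groups (Control 1 with Menopausal 1, and so on) did not meet. Whether a cortex sample came from 1 mouse or from a pool, and the sex and age of the mice, are not given in the sources used here, so p-values measure only the spread between these samples.

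The authors deposited 1 scanner table per array with the intensity of each spot and of its local background in both channels, and these values are raw, per the file headers. The image software, its settings and the gene build are not given in the sources used here. The deposited value table holds 1 log2 ratio per spot and array, normalized by the authors in a way that is not given in the sources used here. Set against the scanner tables, none of its 12 columns was closest to the array of its own label. Each was closest to 1 other array, with 12 arrays matched once each, at a correlation across spots of 0.918 to 0.966 in size, while the correlation with its own array ran from -0.43 to 0.26. The sign at the closest match was negative, so the direction of the table, Alexa Fluor 546 over Alexa Fluor 647, was read from the values. Its column medians ran from -0.07 to 0.10, and its scaling stays unknown. The scan names inside the scanner tables carry a pair of sample codes for each array, and the 6 codes matched the 6 labelled cortex samples one to one, so the scanner tables were used. The value table served only as an alternative, under its own labels, for counts and gene lists. Every direction between groups therefore rests on the labels of the scanner tables, and the mismatch was left unresolved.

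The array holds 31200 spots in 48 blocks, with 15600 probes spotted as 2 adjacent copies. The platform's annotation numbers probes in an order other than that of the scanner tables. Of 64 possible layouts, a mirrored one was chosen from the data: different probes of 1 gene had correlated brightness at r = 0.469 across pairs of probes, against 0.0642 for the next layout. Ribosomal protein probes had a mean brightness percentile of 0.884, against at most 0.625 with any other layout. With this layout the profiles of different probes of 1 gene over the 6 samples had a median correlation between 0.349 and 0.506 in each of the 4 rows of blocks. The layout was chosen after the values were seen, and every gene name rests on it. The annotation listed 9445 probes, 9191 with 1 gene symbol and 254 with several, and left 6155 unnamed here. Symbols were updated through gene identifiers in the GRCm38.p6 gene table for 9085 probes and kept as given for 106. No coordinates are given, because the files name no genome build.

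Computed here with limma 3.58.1 in R 4.3.3: the spot median was corrected by normexp with an offset of 50, log2 ratios (Alexa Fluor 647 over Alexa Fluor 546) were normalized within each array by global loess, spots marked abnormal had weight 0, the copies of a probe were averaged and arrays were not scaled to each other. The shorter scan wavelength was taken as Alexa Fluor 546. A probe was kept if its foreground exceeded the local background by over 2 background SDs in at least 6 of the 12 channel measurements of at least 1 group. This kept 7683 probes, 5559 of them with 1 symbol, for 4437 genes. A least-squares fit with a dye term for each probe turned the 12 ratios into 6 values, 1 per cortex sample, relative to the mean of the 6. Menopausal and control values, 3 against 3, were compared with limma's moderated statistic with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Differences among the 3 samples of a group were tested with limma's moderated F statistic on the 12 arrays, whose 6 residual degrees of freedom measure the spread between arrays of the same RNA, a technical error. Gene lists were tested with camera at a preset correlation of 0.01 over the lists with at least 3 measured genes, using for each gene its brightest probe. Of 34 lists 20 could be tested, since 242 of their 537 genes were on the array and 180 had a kept probe.

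The design, the tests, the lists and the rule for named genes were set before the data were examined. The rule named the 12 genes with the largest rise and fall past the threshold. Where fewer than 10 passed, each direction was filled to 10 with genes whose groups did not overlap, by smallest unadjusted p. It also named up to 4 members of each described list past the threshold or otherwise the 2 of smallest p, a few key genes, and up to 8 probes with the largest range within each group. The 8 lists described in full were picked after the list results were seen: the 6 with the smallest p, and the oestrogen and proximal tubule lists.

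The steps were tested on simulated data. For menopausal against control, with 200 of 7683 probes changed, the test recovered 38.0% at 1.5-fold, 85.5% at 2-fold and 98.0% at 3-fold. Among the 3 control samples, it recovered 0 of 200 probes at 1.5-fold and 79.5% at 2-fold of 7683. The simulated noise was independent between probes, with array errors shuffled over probes, so these shares need not hold in the data. In the data, the probe of smallest unadjusted p between groups differed by 1.58 and did not pass (limma, adjusted p = 0.540). For the gene lists, over 4437 genes, a shift of 0.20 in 1 list was called in 50 of 50 runs. Another list was called in 2 of them. Here too the simulated noise was independent between genes. In the data the estimated correlation between the genes of a list ran from -0.289 to 0.516, and was 0.459 for fatty acid oxidation. The list runs therefore do not show how often camera with its preset correlation finds such a shift or gives false calls in the data. The alternatives tried were other background corrections, within-array normalizations, filters, dye and block terms, arrays as replicates, a separate-channel fit, array weights, the value table, other list tests, and leaving out each sample and each array. Spot means, the arrays without a repeat mark in the scan name, the arrays of the lower slide range and the combinations of print-tip loess with other settings were added after the data were seen. Figures were drawn with Python 3 and matplotlib.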

Results

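Gene expression was measured in the kidney cortex of mice labelled control or menopausal, 3 cortex samples per group, on 12 arrays that each held a pair of samples in 2 colours. The precision is limited by 3 samples per group and by the number of arrays. Between 16.5% and 76.8% of the spots of a channel exceeded their local background, and 24 to 418 spots per array were marked abnormal. Values are log2, relative to the mean of the 6 samples, and differences are menopausal minus control with the standard error from limma (n = 3 per group). Gene names rest on a probe layout chosen from the brightness of the probes, and groups rest on the labels of the scanner tables, whose arrays do not match the columns of the deposited value table.

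The first comparison asked which genes differ between menopausal and control kidney cortex. No probe passed the test, and the genes named here had groups that did not overlap but failed the adjustment. Havcr1, which encodes the kidney injury molecule of the proximal tubule, had the largest named difference, -0.70 ± 0.17. Hdc, the histidine decarboxylase that makes histamine, differed by -0.66 ± 0.15, and Id1, an inhibitor of basic helix-loop-helix transcription factors, by -0.48 ± 0.13. Eci1, an isomerase of mitochondrial fatty acid oxidation, was 0.55 ± 0.14 higher. Gtf2h1, a subunit of the transcription and repair factor TFIIH, was 0.54 ± 0.13 higher in menopausal samples.

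Among the probes whose groups did not overlap, the 10 genes of smallest p in each direction are named. They were picked with global loess, under which the group difference changed with slide position, as described below. On the higher side they also included Tsc22d1, a leucine zipper transcriptional regulator (0.44 ± 0.10), Rps6, a protein of the small ribosomal subunit (0.41 ± 0.10), and Gatb, a mitochondrial glutamyl-tRNA amidotransferase subunit (0.38 ± 0.08). Id2, a relative of Id1, differed by 0.36 ± 0.09 and the small GTPase gene Nras by 0.35 ± 0.08. Arfgap2, which acts on the small GTPase of Golgi vesicles, was at 0.33 ± 0.08, the splicing regulator gene Tra2b at 0.31 ± 0.08 and Rprd1a, whose protein binds RNA polymerase II, at 0.28 ± 0.07. Those named on the lower side also included F3, the tissue factor that starts coagulation (-0.40 ± 0.11), Cd44, the hyaluronan receptor (-0.37 ± 0.09), and Bub3, a spindle checkpoint gene (-0.37 ± 0.10). Dot1l, a histone H3 methyltransferase, differed by -0.35 ± 0.09, Ehd4, an endocytic trafficking gene, by -0.34 ± 0.09, Raly, which encodes an RNA-binding protein, by -0.34 ± 0.09 and Spred2, an inhibitor of the Ras pathway, by -0.27 ± 0.08. Different probes of a gene did not always give the same value. The 2 other Hdc probes were at -0.47 and 0.02, the 2 other Rps6 probes at 0.06 and 0.16, and the other Nras probe at 0.10. The second Gtf2h1 probe was at 0.29, the second Id2 probe at 0.16 and the second Ehd4 probe at -0.29. The 5 other Tsc22d1 probes lay between 0.23 and 0.45. Each of these other probes was brighter than the named one, except the Hdc probe at -0.47. Cd44 and Ehd4 exceeded background in 4 and 5 of 12 measurements of the control group, in which they were higher, and in 9 and 7 of 12 menopausal ones. Gatb, Tsc22d1, Nras, Rprd1a and Id2 did so in 4, 4, 5, 4 and 2 control and 9, 10, 7, 6 and 6 menopausal measurements. They passed the filter of 6 only through the menopausal group, in which they were higher. Spred2 (6 control, 5 menopausal) passed it only through the control group, in which it was higher.

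**Figure D1:**
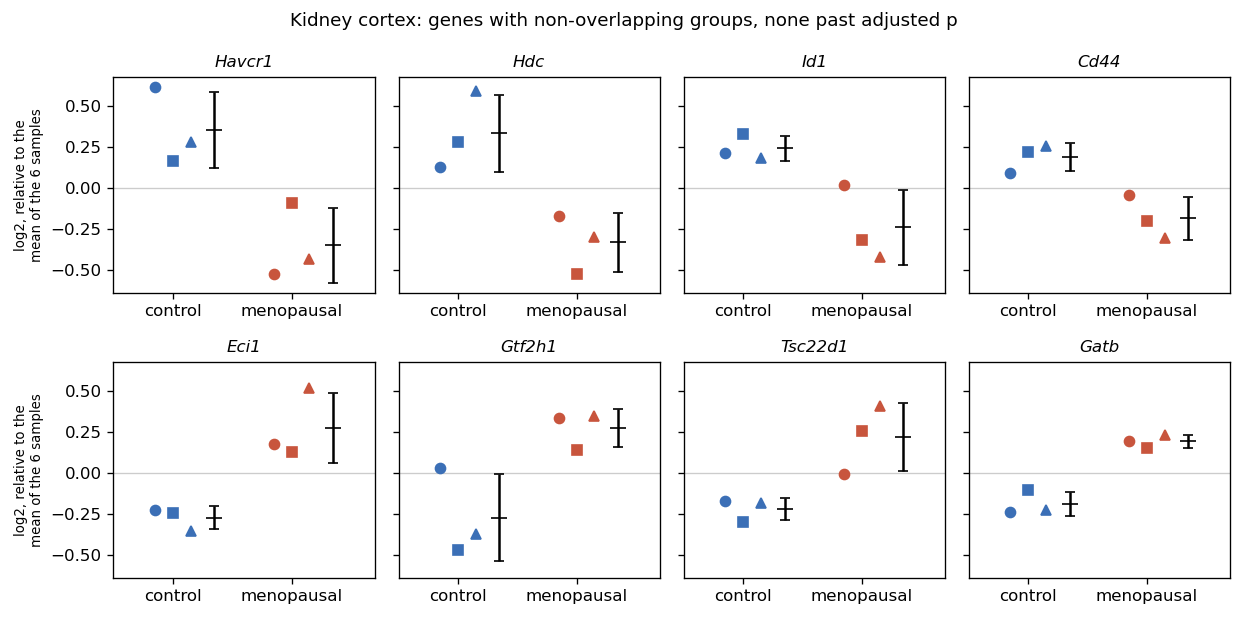
Log2 value of each cortex sample relative to the mean of the 6 samples (vertical axis) in the control and menopausal groups (horizontal axis) for 8 genes whose groups did not overlap. Circles, squares and triangles are samples 1, 2 and 3 of a group and bars are the mean ± SD of 3 samples, and the difference is -0.70 for Havcr1 and 0.55 for Eci1, with none of the genes past the adjusted threshold.

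Of 7683 probes, limma called 0 at an adjusted p of 0.05, the smallest being 0.540. At an unadjusted p under 0.05 there were 574 probes, 346 higher and 228 lower in menopausal samples, where 384 are expected by chance if probes were independent. The split was 195 higher and 180 lower with print-tip loess, 108 and 185 with median centring, and 100 and 104 with scaling between arrays. It was 66 and 221 without background subtraction. With the deposited value table, whose columns match other arrays than their own, it was 95 and 462. With 1 sample left out the count ran from 170 (without Menopausal 2) to 1481 (without Menopausal 3), and 3 of the other splits of the 6 samples, 3 against 3, gave more probes than the real one (603, 825 and 1166). The groups did not overlap at 1010 probes (13.1%), against 10% by chance. Arrays used as replicates also called 0, as did the separate-channel fit, which warned that its estimate of the correlation between channels had not converged. The group difference changed with the position of a probe on the slide, from a median of -0.10 to 0.15 across the 12 columns of blocks, and print-tip loess removed this. The block of a probe accounted for 0.316 of the variance in the difference with global loess and 0.00505 with print-tip loess. The named higher genes all lay in columns with a positive median. Those named lower, except Havcr1 and Id1, lay in columns with a negative one. The pick could thus favour genes whose difference went with the gradient. Each of the 20 named differences except that of Havcr1 was smaller in size with print-tip loess. With print-tip loess 13 of the 20 named differences moved by over 1.5 times, among them Nras to 0.16, Id2 to 0.16, Gtf2h1 to 0.35 and Rprd1a to 0.06, while Havcr1 was at -0.77 and Hdc at -0.60, and without background subtraction Nras, Id2, Gtf2h1 and Spred2 changed sign. Leaving out 1 sample moved 10 of the 20 by over 1.5 times: without Control 2, Nras was at 0.18, Gtf2h1 at 0.24, Cd44 at -0.22, Dot1l at -0.0807, Ehd4 at -0.21 and Spred2 at -0.14. Without Control 3, Tra2b was at 0.19, Rps6 at 0.23 and Raly at -0.22, and Id1 was at -0.80 without Menopausal 1 and at -0.22 without Menopausal 3. Leaving out Menopausal 3 gave 65 probes past the threshold with global loess, 42 higher and 23 lower, among them Tsc22d1, Tra2b, Ehd4 and Spred2, and 0 with print-tip loess.

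**Figure D2:**
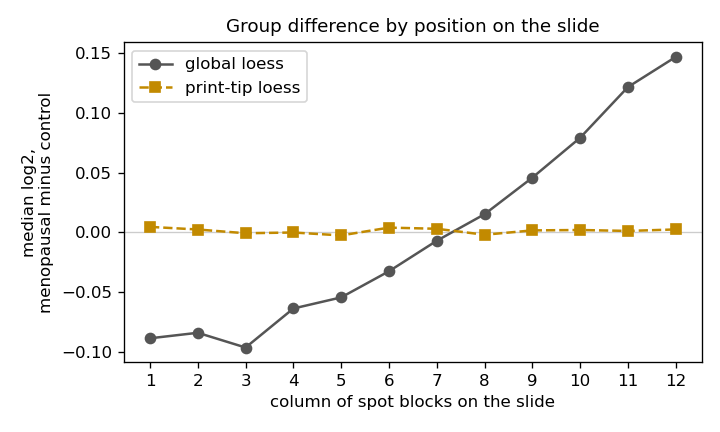
Median log2 difference, menopausal minus control, over the probes in each of the 12 columns of spot blocks of the slide, with global loess (circles) and with print-tip loess (squares). With global loess the medians run from -0.10 to 0.15, and with print-tip loess they run from -0.00251 to 0.00462.

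Among the gene lists, fatty acid oxidation was higher in menopausal samples. All 14 measured genes of this list, which covers mitochondrial and peroxisomal breakdown of fatty acids, had positive differences, with a median of 0.21 (camera with limma, adjusted p = 0.00276). With an estimated correlation between genes of 0.459 the list had an adjusted p = 0.806, so no list passed with an estimated correlation, and fry gave an adjusted p = 0.660. Eci1 (0.55 ± 0.14) and Acot2, a mitochondrial acyl-CoA thioesterase (0.46 ± 0.15), had the smallest p in the list. Acot2 was at 0.29 with print-tip loess and ran from 0.29 to 0.57 with 1 sample or array left out. Adjusted over the list alone, 1 gene passed, Eci1, and 0 did over all probes. The list medians were -0.23, -0.07 and -0.05 in Control 1, 2 and 3 and -0.04, 0.03 and 0.42 in Menopausal 1, 2 and 3. Without Menopausal 3 the median was 0.06 (camera with limma, adjusted p = 0.606), and without Control 1 it was 0.17 (adjusted p = 0.163). Without each of the other samples it lay between 0.21 (Control 2) and 0.36 (Menopausal 1), and the list passed. Of the 10 ways to split the samples 3 against 3, 4 gave as small a camera p, the real split included. With the deposited value table, under its own labels, the list did not pass and its direction turned (adjusted p = 0.782), as did the direction of each other list described below except immediate early genes. This turn is no test of the list if the scanner labels hold, because the table's columns match other arrays. With the slide range as a block the adjusted p was 0.00368, with the repeat mark of the scan as a block 0.00500, and on the 9 arrays of the lower slide range 0.00140. No array across groups was of the higher range or carried a repeat mark. These settings could therefore hardly move the group difference and are no support for the list.

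**Figure D3:**
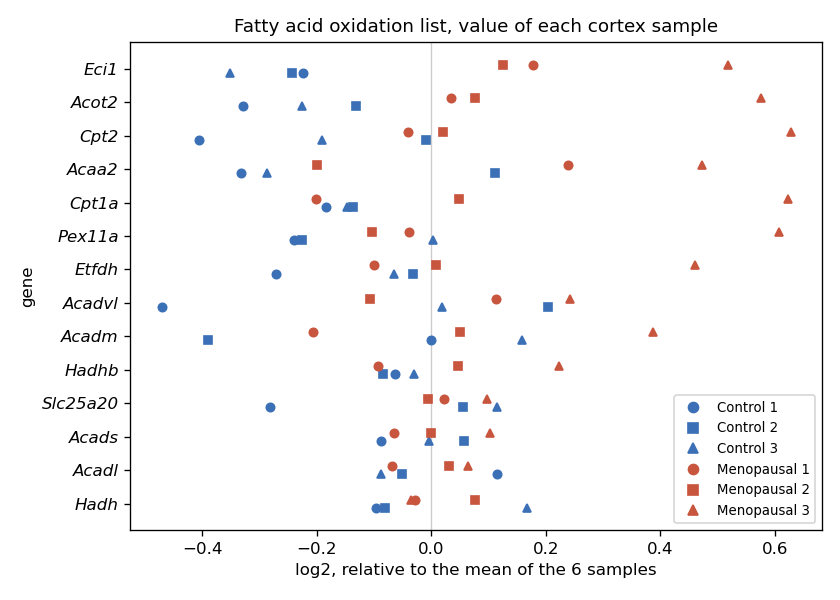
Log2 value of each cortex sample, relative to the mean of the 6 samples (horizontal axis), for the 14 measured genes of the fatty acid oxidation list (vertical axis, ordered by difference). Blue symbols are control and red symbols menopausal samples, and Menopausal 3, with a list median of 0.42, stands to the right of the other samples for most genes.

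The tubular injury list held Havcr1, Cd44 and other genes that injured tubules express. Of its 6 measured genes 4 were lower and 2 higher in menopausal samples, with a median of -0.10, and the list did not pass (camera with limma, adjusted p = 0.158). Adjusted over the list alone, 2 genes passed, Havcr1 (-0.70 ± 0.17) and Cd44 (-0.37 ± 0.09, above background in 4 of 12 control measurements), and 0 did over all probes. With print-tip loess the list median was -0.08 and the list passed (adjusted p = 0.0146). It also passed with plain subtraction (adjusted p = 0.00147), median centring (0.0327), scaling between arrays (0.0486), spot means (0.0111) and probe means (0.0483), and without Control 3 (0.0402) or Menopausal 2 (0.0215). It did not pass with an estimated correlation (adjusted p = 0.806) or fry (0.601), nor when print-tip loess was combined with an estimated correlation (0.620) or with the removal of Menopausal 3 (0.155). In all it stayed uncalled, in the same direction, in 33 of 43 alternatives. Among these were no background filter (adjusted p = 0.447), array weights (0.265) and the fit without Control 2 (0.497). Of 27 ribosomal protein genes 20 were higher, with a median of 0.08 (adjusted p = 0.271). With an estimated correlation of 0.516 the adjusted p was 0.806, and fry gave 0.660. This list passed without Control 2 (adjusted p = 4.68e-06) and without Menopausal 2 (0.0108), and also with plain subtraction (0.0230), median centring (0.00514), arrays as replicates (0.0296) and array weights (0.000455), while its direction turned without Menopausal 1 (0.989). In this list Rplp2, of the large subunit's stalk, was at 0.28 ± 0.12 and Rps3, of the small subunit, at 0.34 ± 0.17. A second Rps3 probe was at -0.06. Among 6 cell cycle genes 5 were lower, with a median of -0.11 (adjusted p = 0.322), and Rrm2, a subunit of ribonucleotide reductase, and Ccna2, a cyclin, both differed by -0.15. Of 13 extracellular matrix genes 8 were lower, with a median of -0.08 (adjusted p = 0.322). The basement membrane genes Lama5 and Col4a2 were at -0.22 ± 0.11 and -0.17 ± 0.10. Of 7 immediate early genes 6 were lower, with a median of -0.08 (adjusted p = 0.322), and the transcription factor genes Jun and Egr1 were at -0.25 ± 0.14 and -0.21 ± 0.16. Ccna2 and Jun changed sign without background subtraction, and Egr1 was at 0.0258 without Control 3. With print-tip loess the median was -0.0542 for cell cycle and -0.0390 for extracellular matrix genes, and Rplp2 was at 0.11, Rps3 at 0.19, Rrm2 at -0.0191 and Col4a2 at -0.0390. With 1 sample or array left out, Rplp2 ran from 0.18 to 0.33, Rps3 from 0.15 to 0.47, Rrm2 from -0.24 to -0.0731, Ccna2 from -0.23 to -0.0190, Lama5 from -0.35 to -0.12, Col4a2 from -0.29 to -0.0914 and Jun from -0.41 to -0.0864.

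Of 5 genes of oestrogen and progesterone signalling 4 were lower, with a median of -0.04 (camera with limma, adjusted p = 0.736), a direction that turned with median centring, without Control 2 and without Menopausal 3. The median was -0.0851 with print-tip loess. Ccnd1, a cyclin gene that oestrogen induces in reproductive tissue, was at -0.20 ± 0.17, and Ltf, the lactoferrin gene, at 0.14 ± 0.11, which was -0.01 with print-tip loess. Esr1, the oestrogen receptor alpha gene, was measured by 2 probes, at -0.01 ± 0.09 and -0.04 ± 0.11, and with print-tip loess the 2 probes went in opposite directions, to 0.13 and -0.13. Mdk, which encodes the heparin-binding growth factor midkine, was at 0.03 ± 0.14 and at -0.14 with print-tip loess. Proximal tubule markers, which report the main cell type of the cortex, had a median of -0.02 with 2 genes higher and 2 lower (adjusted p = 0.754). Gatm, for creatine synthesis, was at -0.24 ± 0.27 and Miox, for inositol breakdown, at 0.08 ± 0.18, and the list and both genes changed sign with scaling between arrays, the list also with median centring and without Control 3, and its median was 0.0243 with print-tip loess. With 1 sample or array left out, Ccnd1 ran from -0.34 to -0.10, Gatm from -0.46 to -0.0246 and Miox from -0.0251 to 0.16. The other 12 lists tested, which included immune cell markers, clock genes and oxidative phosphorylation, had adjusted p from 0.415 to 0.991. In the glucocorticoid response list the median, -0.07, and the mean, 0.06, differed in sign.

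The control arrays asked how far control samples differ from each other. Hbb-b1, the adult beta haemoglobin gene, differed 1.80 and 1.79 in log2 between the highest and lowest control sample at its 2 probes, and was highest in Control 3. Phtf1, a putative homeodomain gene, had the largest range of the named genes, 2.18, from -1.04 in Control 2 to 1.15 in Control 3. Ttc3, an E3 ubiquitin ligase gene (range 1.67), Sgce, the epsilon-sarcoglycan gene (1.49), Lancl2 (1.42), the RNA helicase gene Ddx1 (1.40) and Nfatc4, a calcineurin-dependent transcription factor gene (1.40), were all lowest in Control 2. The 2 other Ttc3 probes had ranges of 0.01 and 0.28, and the other Sgce probe 0.09. In all, 64 probes differed among control samples (limma moderated F, adjusted p from 0.0015 to 0.0355 for the probes of the named genes), 18 of them with a symbol. Print-tip loess called 83, of which 51 were shared, with Sgce and Ddx1 at an adjusted p = 0.0696, and no background subtraction called 0. Without Control 1, Control 2 or Control 3 the count was 4, 19 and 0, without Menopausal 2 it was 167 and without Menopausal 3 it was 32, and single arrays left out gave 6 to 112. Of the 28 alternatives run for each probe, the call held in 21 and 24 for the Hbb-b1 probes of range 1.80 and 1.79. It held in 21 for Phtf1, 20 for Nfatc4, 15 for Ttc3, 14 for Sgce, 13 for Lancl2 and 12 for Ddx1.

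Among the menopausal samples, 5 of the 6 named probes stood highest in Menopausal 3. Slc16a1, a lactate transporter gene, had a range of 1.496 and Sgk1, the serum and glucocorticoid-regulated kinase gene, of 1.40. Gldc, of glycine breakdown, had a range of 1.04, Fkbp5, a co-chaperone of the glucocorticoid receptor, of 0.87 and Arntl, a core gene of the circadian clock, of 0.75. Menopausal 3 was at 1.14 for Slc16a1, 1.18 for Sgk1, 0.69 for Gldc, 0.63 for Fkbp5 and 0.53 for Arntl. Hbb-b1 was highest in Menopausal 1, with a range of 1.44 at 1 of its 2 probes and 1.36 at the other, which did not pass. These were the 6 probes with a symbol among the 15 that differed (limma moderated F, adjusted p from 0.0234 to 0.0494 for the named probes). Print-tip loess called 29, of which 14 were shared, and no background subtraction called 0. Without Control 1, Control 3 or Menopausal 3 the count was 0, and without Menopausal 1 it was 1, and single arrays left out gave 0 to 15. Under the alternatives the call held in only 3 of 27 for Arntl, 4 of 27 for Fkbp5, 5 of 28 for Gldc, 11 of 28 for Hbb-b1, 13 of 27 for Slc16a1 and 14 of 28 for Sgk1. The 2 other Gldc probes had ranges of 0.80 and 0.52 and did not pass with global loess. With print-tip loess the probe of range 0.80 passed (limma moderated F, adjusted p = 0.0260), as it did among control samples (0.0415).

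**Figure D4:**
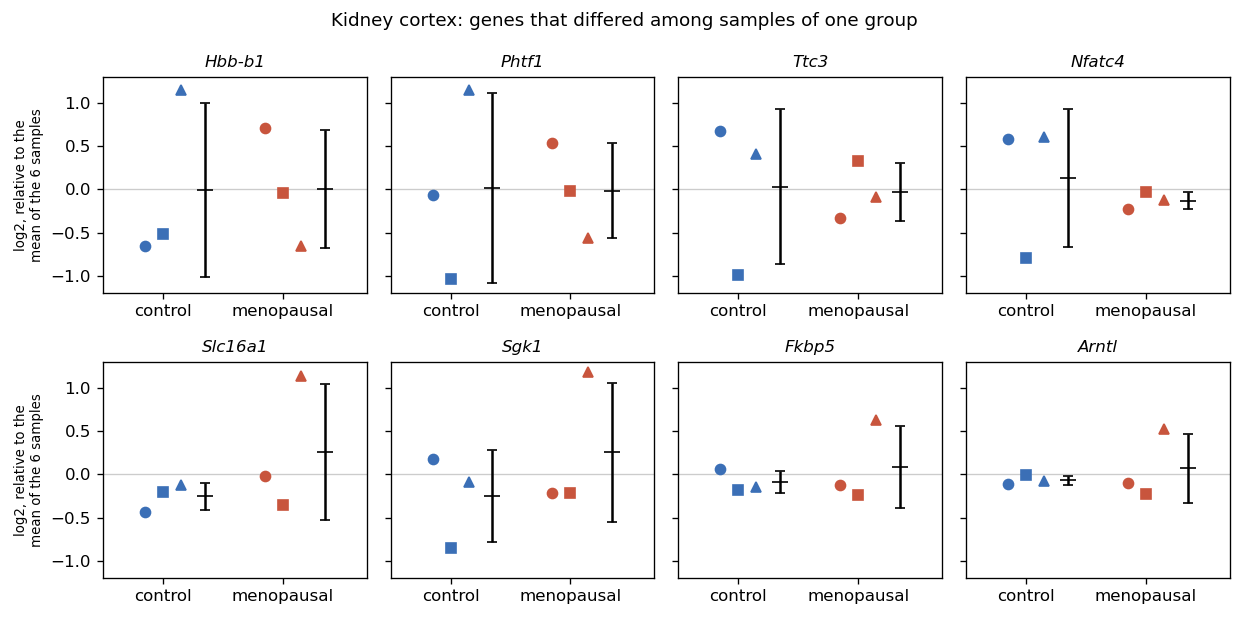
Log2 value of each cortex sample, relative to the mean of the 6 samples (vertical axis), by group (horizontal axis), for 4 genes that differed among control samples and 4 that differed among menopausal samples. Circles, squares and triangles are samples 1, 2 and 3 of a group and bars are the mean ± SD of 3 samples, with Sgk1 at 1.18 in Menopausal 3 and Hbb-b1 at 1.15 in Control 3.

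The spread between samples was compared between the groups. The median SD over probes was 0.13 among control and 0.13 among menopausal samples, a ratio of 1.01 (exact permutation over 10 splits, two-sided p = 1, the smallest possible being 0.1). A dye effect was found at 2092 of 7683 probes with global loess and at 0 with print-tip loess (limma).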

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

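Spot means, the arrays without a repeat mark, the arrays of the lower slide range, and print-tip loess together with a replicate block, an estimated correlation or the removal of Menopausal 3 were chosen after seeing the data. The cause of the changes given here was not tested, unless fewer samples, arrays or probes account for them by construction. Low signal over background limited the values: 9 of the 49 named probes exceeded background in all 12 measurements of both groups, and Id2 did so in 2 of 12 control measurements.

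The count of probes past the threshold between menopausal and control samples was 0 under every alternative run except without Menopausal 3, so left-out samples and arrays gave 0 to 65. With the sample number as a replicate block the count was 0, 1 gene list passed and 255 probes were higher and 143 lower at an unadjusted p under 0.05. The labels tie the numbers to no animal, litter or batch. Deviations of same-numbered samples correlated at -0.43, -0.46 and -0.06, and samples did not each correlate best with their own number, but same-numbered samples never met on an array and deviations were centred within groups, so these values do not decide whether the numbers pair the samples. The block changed no call. Of the 15 pairs of samples, Control 1 with Menopausal 2 had the smallest SD of the difference, 0.166, and their deviations correlated at 0.502. The closest pair within a group, Menopausal 1 with Menopausal 2, was at 0.217, and each of these pairs met on an array. Control 3 with Menopausal 3, which did not meet, had the largest SD, 0.302. The closest samples thus came from different groups, as did the farthest.

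Probes that differed among control samples numbered 0 without background subtraction, without a dye term and with the authors' value table, 16 with scaling between arrays, 36 with no dim filter, 146 with the stricter filter, 9 on the 8 arrays without a repeat mark, 37 on the 9 arrays of the lower slide range, and 0 to 167 with a sample or array left out. Among menopausal samples the count was 0 without background subtraction, with scaling, without a dye term, with the value table and on the lower slide range, 3 with plain subtraction, 109 with median centring, 29 with print-tip loess, 2 with no dim filter, and 0 to 15 with a sample or array left out. The ratio of spreads was 1.37 with median centring, 1.24 with the value table, 1.33 on the lower slide range, and 0.702 to 1.35 with a sample or array left out. Probes with a dye effect numbered 652 without background subtraction, 0 with print-tip loess and with the value table, 903 with scaling, 1373 with no dim filter, 1271 without repeat marks, 1063 on the lower slide range, and 0 to 2424 with a sample or array left out.

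The number of gene lists past the threshold was 2 without background subtraction, with print-tip loess, scaling, arrays as replicates, array weights, probe means, spot means and print-tip loess with a replicate block. It was 3 with plain subtraction, 5 with median centring, 0 with an estimated correlation (also with print-tip loess), with fry and with the value table, and 0 to 4 with a sample or array left out. The fatty acid oxidation list had an adjusted p between 1.45e-05 and 0.806 over the alternatives and kept its call and direction in 36 of 43. It lost the call among others with print-tip loess without Menopausal 3 (adjusted p = 0.590). Tubular injury gained a call with plain subtraction (adjusted p = 0.00147), median centring (0.0327), print-tip loess (0.0146; 0.0181 with a replicate block), scaling (0.0486), probe means (0.0483), spot means (0.0111), without Control 3 (0.0402) and without Menopausal 2 (0.0215). Ribosomal proteins gained it with plain subtraction (0.0230), median centring (0.00514), arrays as replicates (0.0296), array weights (0.000455), without Control 2 (4.68e-06), without Menopausal 2 (0.0108), with single arrays left out in 2 cases (0.0451 and 0.00519) and with print-tip loess without Menopausal 3 (0.0273). Tubular injury stayed uncalled, in the same direction, in 33 of 43 alternatives and ribosomal proteins in 32 of 43. No other described list gained a call. With the value table, under its own labels, the direction turned for fatty acid oxidation, tubular injury, ribosomal proteins and cell cycle (adjusted p = 0.782 each), extracellular matrix (0.386), oestrogen and progesterone signalling (0.290) and proximal tubule markers (0.1504). These turns bear on the lists only if the table's labels, and not those of the scanner tables, hold. Median centring turned the oestrogen list (0.796) and proximal tubule markers (0.771), and scaling turned the latter (0.726). With samples or arrays left out, adjusted p ran from 4.68e-06 to 0.989 for ribosomal proteins, from 0.527 to 0.948 for the oestrogen list and from 0.726 to 0.989 for proximal tubule markers. The direction turned for ribosomal proteins without Menopausal 1 (0.989), for the oestrogen list without Control 2 (0.869) and without Menopausal 3 (0.905), and for proximal tubule markers without Control 3 (0.916) and with 1 array left out (0.739).

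Named differences changed sign as follows. Without background subtraction Nras was -0.0222, Id2 -0.0362, Gtf2h1 -0.0205, Spred2 0.0578, Ccna2 0.0273, Jun 0.0685, Ltf -0.00735 and Esr1 0.0108. Plain subtraction gave 0.0730 for Esr1 and -0.29 for Mdk. Print-tip loess gave -0.00503 for Ltf, 0.13 for Esr1 and -0.14 for Mdk. Scaling gave 0.0809 for Gatm, -0.0136 for Miox, 0.0512 for Esr1 and -0.0611 for Mdk. The separate-channel fit, which did not converge fully, gave 0.0469 for the second Esr1 probe, and array weights 0.000514 for the first. With samples or arrays left out, Egr1 ran from -0.41 to 0.0258 (turned without Control 3), Ltf from -0.00971 (turned without Menopausal 1) to 0.28, Miox from -0.0251 (turned without Menopausal 2) to 0.16, Mdk from -0.13 to 0.28 and the Esr1 probes from -0.0901 to 0.11 and from -0.11 to 0.10.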

Other observations

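The tests of other splits of the samples, of a slide gradient and of proximal tubule RNA behind the fatty acid oxidation difference, and of a fault on 1 array, the clock and glucocorticoids behind the genes of Menopausal 3 were chosen after the results were seen. The named rule left out several genes of fatty acid oxidation that were picked here after their values were seen. Cpt2 and Cpt1a, which move fatty acids into mitochondria, differed between groups by 0.40 ± 0.19 and 0.31 ± 0.18 (n = 3 per group), and the peroxisome gene Pex11a by 0.31 ± 0.19, none past the threshold. The probe with the smallest unadjusted p, number 2657, has no symbol here and was 1.58 ± 0.28 higher in menopausal samples (limma, adjusted p = 0.540; 1.67 with print-tip loess). Its values were -1.21, -0.48 and -0.69 in control and 0.55, 0.29 and 1.54 in menopausal samples.

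The 6 cortex samples can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probes past the threshold and the highest of the other splits 0, and since no split can give fewer than 0, the count of 10 of 10 says nothing about grouping. With print-tip loess the split of Control 1, Control 3 and Menopausal 2 against the rest gave 68 probes, a structure of the samples that does not follow the groups. The real split gave 1 gene list past the threshold, the highest other gave 4, and 6 of 10 gave as many.

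The fatty acid oxidation list was higher in menopausal samples by a median of 0.21. A gradient across the slide would have been removed by print-tip loess, with which the median was 0.23. Without Menopausal 3 the median was 0.0620, so the difference may belong largely to that sample, although leaving out Control 1 also ended the call (0.17). The proximal tubule markers, at a median of -0.0191 (0.0243 with print-tip loess) with 2 higher and 2 lower, do not decide whether more proximal tubule RNA was in the menopausal samples, and an effect of the menopausal state itself stays open. The negative log10 of the list p was 3.86 in the real split and 5.87 in the highest other. It was as large in 4 of 10 splits, the real one included. With print-tip loess it was 4.07 in the real split. It was then 4.49 with Control 1, Control 2 and Menopausal 2 against the rest, and 6.54 with Control 1, Control 3 and Menopausal 1. A list p as small was therefore not particular to the split into control and menopausal samples.

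The Hbb-b1 profile, at a mean of -0.55, -0.64 and 1.09 in Control 1, 2 and 3 and 0.77, -0.04 and -0.63 in Menopausal 1, 2 and 3, recurred in 32 of the 62 other probes that differed among control samples, at r above 0.9, a limit chosen after seeing the data. Of these, 31 have no symbol here, and the other is the Phtf1 probe named above for its range among control samples. A smear or dust on 1 array would have ended the pattern when that array was left out, yet the lowest range over the control samples was 1.48, against 1.73 with all arrays. The range thus did not rest on 1 array. The Hbb-b1 probes had passed an F test that favours agreement between arrays, so this outcome was likely beforehand. A candidate explanation is a different amount of blood in the cortex samples: Alas2, the haem synthesis gene of red cell precursors and the 1 other blood marker measured, correlated with the profile at r = 0.794 over 6 samples (exact permutation p = 0.0722, rho = 0.657 with exact permutation p = 0.175, r = 0.970 without the 2 farthest samples, 1 relation computed). This lies just under the limit of 0.8 that had been set for it, the range of Alas2 among control samples was 0.22, and the kidney holds blood in any case, so blood stays open, and no explanation other than blood and a fault on 1 array was tested.

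Slc16a1, Sgk1, Gldc, Fkbp5 and Arntl set Menopausal 3 apart, by a mean of 1.05 above the other menopausal samples, although the call held for Arntl in 3 of 27 alternatives and for Fkbp5 in 4. Sgk1 also had a range of 1.02 among control samples (limma moderated F, adjusted p = 0.0786, and 0.0033 with print-tip loess). The control range was 0.72 for Gldc, 0.30 for Slc16a1, 0.23 for Fkbp5 and 0.11 for Arntl. With each array left out in turn the lowest mean excess was 0.98, so the excess did not rest on 1 array. The genes had been picked by an F test on the same arrays that favours agreement between them. This outcome was therefore likely beforehand and weighs little against a fault on 1 array. Another phase of the circadian clock at sampling could raise Arntl and lower Nr1d2, a repressor of Arntl, and Nr1d2 was at -0.80 in Menopausal 3, yet it did not pass among menopausal samples (limma moderated F, adjusted p = 0.241). Tef, the remaining measured gene of the clock list, was at -0.09 in Menopausal 3 and -0.07 in Menopausal 1 (limma moderated F, adjusted p = 0.827). The clock thus stays open. Of the 4 other measured glucocorticoid response genes 2 were highest in Menopausal 3, Nfkbia (0.40) and Klf9 (0.30), while Mt1 (-0.06) and Mt2 (-0.34) were not, so glucocorticoid exposure at sampling also stays open. Time of day, feeding and handling at sampling are not given in the sources used here.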
